A study of Mus musculus with 20 samples.

How the data were processed

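Replication timing was measured in mouse cells on 20 genomic microarrays, with 2 arrays for each of 10 cell types. The assay was BrdU-IP Repli-chip. Cells were fed the thymidine analogue BrdU, sorted by DNA content into an early and a late S-phase fraction, and the newly made DNA of each fraction was recovered with an antibody to BrdU, amplified, labelled with Cy3 or Cy5 and hybridised together to 1 array, per the labels' protocols. The ratio of early to late signal at a probe is high where the locus replicates early in S phase. In every group, replicate 1 carried the early fraction in Cy3 and replicate 2 carried it in Cy5, per the labels. The labels number the arrays of a group as biological replicates and say no more about separate cultures or animals, except that the epiblast stem cell (EpiSC) arrays are of passages 4 and 5 and that each sex of embryonic fibroblast appears to be 1 isolate. The p-values given here therefore measure only the spread between these samples, which may be technical. For ESCs and day 2 alone, chromosome 8 signal described below argues against 2 arrays of the same DNA.

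The files were Agilent Feature Extraction 10.7.3.1 output (protocol CGH_107_Sep09) of a SurePrint mouse comparative genomic hybridisation array with probe positions on genome build mm9, per the file headers. The processed spot intensity of each channel was background-subtracted with spatial detrending and dye-normalized with a linear method within each array, per the file headers, and nothing in them records a step between arrays. The deposited log10 ratio of Cy5 over Cy3 was used only as a check: it differed by more than 0.001 from the ratio of the processed intensities at no more than 0.0264% of the probes of an array. Flags for outlier, dim and saturated spots came from the same files, per the file headers. Any further normalization by the submitters is not given in the sources used here.

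Each array had 180880 spots, of which 6575 were controls and were left out. Outlier spots (139 to 629 per array) were dropped, saturated spots (0 to 23) were kept, and spots of the same probe were averaged, which left 170305 probes: 161460 on autosomes, 8723 on the X chromosome and 122 on the Y chromosome. Between 94.5% and 99.6% of the probes were well above background in the early channel of an array and 97.6% to 99.9% in the late channel, with 145936 probes (85.7%) well above background in both channels on all 20 arrays. The number of arrays limits the precision of every value.

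The processed intensities were turned into log2(early S/late S) with the dye orientation of the labels. Each array was centred on the median of its autosomal probes. Probe values were averaged over non-overlapping windows of 200 kb that held at least 5 probes, which gave 11941 windows, 11256 of them autosomal and 685 on the X chromosome, with a median of 15 probes. Each array was then scaled so that the standard deviation (SD) of its autosomal windows equalled the geometric mean over all arrays, 1.67. Before scaling that SD ran from 1.18 in a male fibroblast array to 2.44 in an ESC array. A positive window value means early replication relative to the median autosomal probe.

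Window values were fitted with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) on all 20 arrays with 1 mean per group and 1 pooled spread (10 residual degrees of freedom, 17.4 in total after moderation). A window was called at a Benjamini-Hochberg adjusted p under 0.05 over all windows and an absolute difference of at least 0.5. A called window was said to have switched where the sign of its mean also changed between the groups. Called windows in the same direction were joined into regions across at most 1 uncalled window. Chromosome means were fitted in the same way over the 20 chromosomes, where the spread was pooled over chromosomes. The relation of the X chromosome mean to the day of differentiation, with undifferentiated cells as day 0, was tested with two-sided permutation tests of 100000 resamples. Arrays were shuffled singly although the 2 arrays of a group share a day. Permutation p-values therefore treat these arrays as independent and can be too small. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

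Genes were placed by the midpoint of the probes that carried their symbol in the files and took the value of the window holding that point. Of 18700 names on probes, 18687 could be placed, 15425 of these matched a symbol and 695 a synonym in a reference gene table of assembly GRCm38.p6, 15 matched a gene of another chromosome and 2552 matched none and kept the name of the files. Because that assembly is not the build of the arrays, its coordinates were not used, only its gene names and the order of neighbouring genes. Pou5f1, Actb and Xist had no probe with their own symbol and were placed between the probes of their neighbours. Dppa4, Sox2, Sox1 and Twist1 could not be placed and are not analysed here.

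The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is said below to be chosen later. The 14 gene lists were naive pluripotency (13 of 24 members with probes), primed epiblast (14 of 23), neurectoderm (17 of 30), mesoderm and endoderm (14 of 22), fibroblast (21 of 24), housekeeping (14 of 20), imprinted genes (16 of 20), genes that escape X inactivation (8 of 10), Hox genes (13), olfactory receptors (76), vomeronasal receptors (90, of which 87 lay in tested windows), protocadherins (1), keratins (32) and histone clusters (4). The X chromosome was tested beside them as a region. Members that share a window share its value: the 13 Hox genes lie in 5 windows and the 32 keratins in 9. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a comparison. The list test of day 2 was not among those fixed beforehand and was added to them. Named genes were, for each main comparison, the called members of the lists, up to the 5 with the largest absolute difference per list and direction, a fixed set (Zfp42, Dppa2, Esrrb, Klf4, Nanog, Pou5f1, Fgf5, Otx2, Pax6, Ptn, Ednrb, Dach1, Col1a2, Actb and Xist) in any case, and the 5 regions with the highest and the 5 with the lowest difference at their extreme window, at least 1 Mb apart and changed the same way in both dye orientations. Regions were named by the gene that most probes of the extreme window carried, and some of these genes and regions are not reported here.

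The median window of a comparison was not 0 and depended on centring and scaling. Against undifferentiated cells that median was 0.33 at day 2, -0.17 at day 7, -0.11 in EpiSCs and -0.14 in female fibroblasts. It was 0.50, -0.031, 0.0086 and 0.47 without scaling, and 0.067, -0.088, -0.064 and -0.16 with centring on the autosomal mean. Differences of single genes, regions and list medians in these 4 comparisons are therefore given relative to that median, while calls, counts, standard errors (SE) and adjusted p-values belong to the fitted difference before the subtraction. All other differences, and all values under the alternatives below, are as fitted.

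Steps were tested on simulated data before use. For day 7 against undifferentiated cells, with 50 windows of each size changed among 11941, the fit called 18% of windows changed by 0.5, 86% of those changed by 1 and 100% of those changed by 2 or 3, and called 9 unchanged windows. For female against male fibroblasts the shares were 20%, 94%, 100% and 100%, with 14 unchanged windows called. In 300 simulations of an X mean lower by 0.6, the difference was called in 100% with a median estimate of -0.60 and 30 calls of unchanged chromosomes in all. The number of simulations was raised from 1 to 300 after the first result was seen. A list shifted by 0.5 was called with 0 other lists. The simulated windows varied independently of each other, while the estimated correlation within the real lists ran from 0.0394 (imprinted) to 0.704 (histone). False calls that come from correlated windows or list members were therefore not tested.

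The alternatives were no scaling between arrays, normexp background correction (offset 50) on the mean and background intensities, loess within arrays, centring on all probes, windows of 100 kb and 500 kb, window medians, leaving out dim probes, at least 10 probes per window, a size minimum of 0 or 1, only the compared groups in the fit, slide as a fixed or random block, the replicate number as a block, and leaving out each array in turn. Quantile normalization, centring on the autosomal mean, scan day as a block, the X spread taken alone, and only days 2 to 7 in the relation with day were chosen after seeing the data. So was the use of the alternatives on the X mean outside day 7, EpiSCs and female fibroblasts against undifferentiated cells and female against male fibroblasts. The arrays lay on 6 slides scanned on 4 days. ESC and days 2 to 7 shared 4 slides, while the 4 fibroblast arrays lay on 1 slide and the 2 EpiSC arrays on another.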

Results

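The data follow replication timing as mouse embryonic stem cells (ESCs) leave the naive state and form neurectoderm, and set these cells beside epiblast stem cells (EpiSCs) and embryonic fibroblasts (MEFs). There were 10 groups with 2 arrays each. CBMS1 ESCs, a line of CBA/MsM background, were grown undifferentiated in 2i/LIF, a medium with 2 kinase inhibitors and leukaemia inhibitory factor that holds them in the naive state. Arrays of the same line were made at day 2 of differentiation, when the cells had become epiblast-like cells (EpiLCs), and at days 3, 4, 5, 6 and 7. Those later days were days 1 to 5 of culture as aggregates, by which time the labels describe neurectoderm. EpiSCs, the stem cells of the epiblast after implantation, were female and grown in Activin and FGF on fibroblast feeders. MEFs were female or male. EpiSCs and MEFs were of C57BL6 background, so strain, line, slide and scan day changed together with cell type in every comparison of these cells with CBMS1, and batch and group cannot be told apart there. The labels do not give the sex of CBMS1. Total signal of X probes, relative to autosomal probes of like timing, was -0.15 in ESCs and -0.14 in female MEFs on the log2 scale, against -0.94 in male MEFs (n = 2 each). The median processed intensity of an array was 767 to 1486 in the early channel and 723 to 1197 in the late channel. Genes take the value of their 200 kb window, in log2(early/late) units on build mm9, and windows are neighbours on chromosomes and thus not independent replicates.

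Day 2 lay closer to ESCs (r = 0.918 across autosomal windows) than to EpiSCs (r = 0.883), and day 7 closer to EpiSCs (r = 0.917) than to ESCs (r = 0.832). EpiSCs correlated with day 5 at r = 0.939 and with ESCs at r = 0.868. Female and male MEFs were nearly alike (r = 0.992) and correlated with ESCs at r = 0.738 and 0.724, and with day 2 at r = 0.717 and 0.696, the lowest value for either sex. Days 6 and 7 correlated at r = 0.987. Replicate arrays, which carried opposite dyes, correlated at 0.962 in EpiSCs to 0.996 at day 6.

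**Figure D1:**
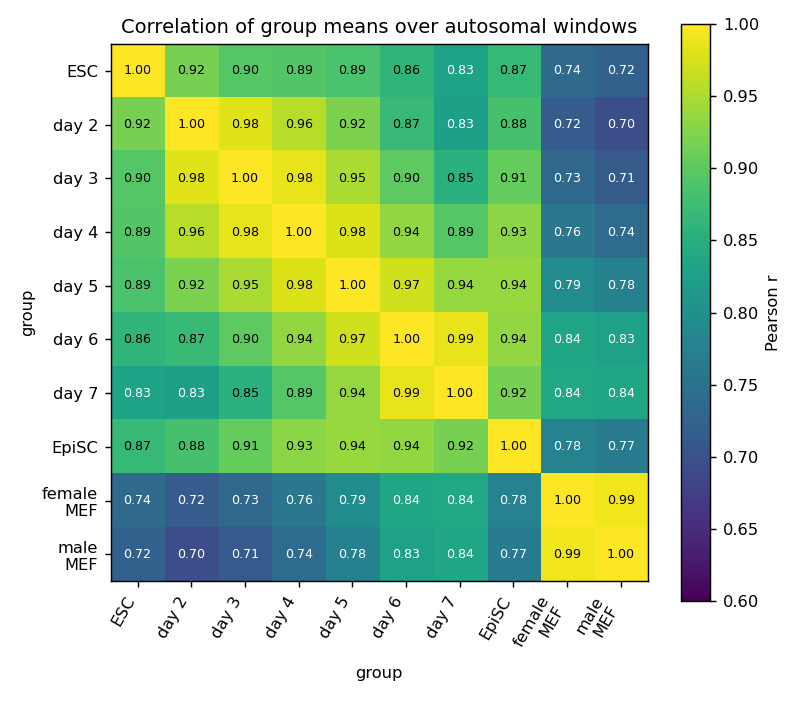
Pearson correlation of mean replication timing across 11256 autosomal windows between the 10 cell types (rows and columns, n = 2 arrays each, colour gives r). The pair of MEF sexes (0.992) and days 6 and 7 (0.987) stand out as alike, and day 2 and male MEFs (0.696) as farthest apart.

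The first comparison, day 2 against ESCs, asks what changes when naive cells become EpiLCs. The window of Fgf5, a growth factor gene that marks the primed epiblast (chromosome 5, 98600001 to 98800000), went from late to early replication, from -2.06 ± 0.04 to 0.66 ± 0.09 (mean ± SD, n = 2). The window of Zfp42 (Rex1), a marker of naive cells (chromosome 8, 44200001 to 44400000), went from 1.74 ± 0.0016 to 0.60 ± 0.11. The median window rose by 0.33, and relative to it Fgf5 lay 2.40 earlier (SE 0.19, limma adjusted p = 1.09e-08) and Zfp42 stood at -1.46 (SE 0.12, adjusted p = 1.19e-06). Total signal of chromosome 8, which holds Zfp42 and Klf2, differed by 0.31 between the 2 ESC arrays, and that of chromosome 12, which holds Esrrb, by -0.21. Of 14 measured genes of the primed epiblast, 12 were called earlier and 0 later. Otx2, a homeobox factor of the epiblast and forebrain, lay 1.01 above the median window, T (Brachyury), a mesoderm factor first seen in the primed epiblast, 1.07, and the Nodal antagonist Lefty2 0.70. The list was called earlier with camera (adjusted p = 0.0142, median 0.58 above the median window), but adjusted p = 0.804 with an estimated correlation, and its call was lost without scaling. Of the 12 earlier members 8 lay over 0.5 above the median window. With quantile normalization 5 were called earlier and 0 later, and the fitted median was 0.20 in place of 0.91. Pou5f1 (Oct4), placed between its neighbours, was called earlier at 0.59. The shift was larger among early windows. The 95th percentile of autosomal windows was 1.84 in ESCs and 2.57 at day 2, and the 5th was -2.63 and -2.32. Subtracting the median window therefore leaves part of the shift in genes that were early in ESCs. Actb, placed between its neighbours, went from 1.62 ± 0.03 to 2.57 ± 0.14.

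Of 13 measured genes of naive pluripotency, 5 were called later at day 2 and 3 earlier. Tet2, an enzyme that oxidises methylated cytosine, stood at -2.33, the Krüppel-like factors Klf4 and Klf5 at -1.60 and -1.44, and Tfcp2l1, a factor of the naive network, at -0.95. The 3 called earlier were Klf2 (0.61), Nanog (0.28) and Nr5a2 (0.26), and all 3 calls were lost with quantile normalization, where Nr5a2 turned to a fitted -0.15. The list was called later (adjusted p = 0.0142, median -0.76), but adjusted p = 0.804 with an estimated correlation, and its call was lost when members placed between neighbours were added. Esrrb (-0.76) and Dppa2 (0.16) were not called.

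Neurectoderm genes were called earlier in 11 of 17 cases and later in 2. The nuclear receptors Nr2f2 (2.04, SE 0.15, adjusted p = 4.22e-09) and Nr2f1 (1.01), the POU factor Pou3f3 (1.40) and Meis2 (0.98) were among the earlier genes, and the adhesion gene Ncam1 (-1.64) was later. The list as a whole did not pass (adjusted p = 0.133). Of mesoderm and endoderm genes, 4 were called earlier and 3 later of 14. Foxa2, an endoderm factor, lay 1.79 earlier and Kdr, the VEGF receptor of blood vessel precursors, stood at -2.45 (SE 0.14, adjusted p = 5.71e-09). That list was not called (adjusted p = 0.539), and its fitted median (0.17) had the opposite sign to its test. Imprinted genes were called earlier in 9 of 16 cases and later in 1 (adjusted p = 0.539), among them Snrpn (1.03) and Peg10 (0.95), with Plagl1 (-1.75) later. Fibroblast genes were 10 earlier and 1 later of 21 (adjusted p = 0.224), with Col3a1 at 0.68 and Fn1, fibronectin, at -1.34. All 13 Hox genes (adjusted p = 0.133), 10 of 14 housekeeping genes (adjusted p = 0.151) and 4 of 8 genes that escape X inactivation (adjusted p = 0.692) were called earlier. With quantile normalization the calls were 5 Hox genes earlier, 4 housekeeping genes earlier and 1 later, and 1 escape gene earlier and 2 later. The housekeeping list was called earlier when members placed between neighbours were added (adjusted p = 0.0282, but adjusted p = 0.789 with an estimated correlation). Keratins were 2 earlier and 7 later of 32 (adjusted p = 0.224, but called later without scaling with adjusted p = 0.0385, and 0.82 with an estimated correlation), olfactory receptors 19 earlier and 14 later of 76 (adjusted p = 0.356) and vomeronasal receptors 25 earlier and 13 later of 87 (adjusted p = 0.224). Both receptor lists had fitted medians above 0 (0.14 and 0.18) and tests toward later. All of these counts come partly with the shift of 0.33. Called members that also lay over 0.5 from the median window were 7 earlier and 2 later for neurectoderm, 3 and 3 for mesoderm and endoderm, 6 and 1 for imprinted, 2 and 1 for fibroblast, 5 and 0 for Hox, 6 and 0 for housekeeping and 1 and 0 for escape genes, 0 and 7 for keratins, 7 and 14 for olfactory and 7 and 13 for vomeronasal receptors. With quantile normalization the calls were 3 earlier and 2 later for fibroblast genes, 14 and 13 for olfactory and 10 and 18 for vomeronasal receptors. Of 4 histone genes 1 was called earlier (adjusted p = 0.883, test toward later against a fitted median of 0.22), and the protocadherin measured was not called.

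In all, 5575 windows (46.7%) differed at day 2, 4079 earlier and 1496 later. This split depended on centring: 73.2% of calls were earlier, but 49.5% (2336 earlier, 2386 later) with arrays centred on the autosomal mean and 47.9% (1971 earlier, 2144 later) with quantile normalization, which shared 3313 of the calls in direction. Among the highest regions were those of Emb, a cell adhesion gene (chromosome 13, 118000001 to 118200000, 3.02 above the median window), Zfp644 (chromosome 5, 107000001 to 107200000, 2.75) and Plxdc2 (chromosome 2, 16600001 to 16800000, 2.72). Among the lowest were those of Abca1, a cholesterol exporter (chromosome 4, 53000001 to 53200000, -4.11), and Trps1, a GATA-type factor (chromosome 15, 50600001 to 50800000, -3.01). With slide as a block 5276 windows were called, and with scan day as a block 5367. In each of the 14 lists the count of called members adjusted over the list alone equalled that over all windows, in this comparison and in those of day 7, EpiSCs and female MEFs with ESCs.

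Day 7 against ESCs asks what changes by the neurectoderm stage. Zfp42 replicated late, at -2.38 ± 0.03 (n = 2), and stood at -3.95 relative to the median window (SE 0.12, limma adjusted p = 4.43e-13). Dppa2, a gene of the early embryo (chromosome 16, 48200001 to 48400000), went from 1.25 ± 0.06 to -2.10 ± 0.17 (relative difference -3.18, SE 0.19, adjusted p = 1.05e-10). Nanog (chromosome 6, 122600001 to 122800000) went from 1.70 ± 0.07 to -0.34 ± 0.22 (-1.87). Ptn, a growth factor of the developing brain (chromosome 6, 36600001 to 36800000), went the other way, from -2.59 ± 0.011 to 0.76 ± 0.26 (3.52, SE 0.34, adjusted p = 1.48e-07). Of 13 genes of naive pluripotency, 10 were called later and 0 earlier, Tet2 (-2.61), Klf5 (-2.32) and Klf4 (-0.92) among them, and the list was called later (adjusted p = 2.71e-05, but adjusted p = 0.268 with an estimated correlation). Esrrb (-0.30) was not called.

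Neurectoderm genes were called earlier in 10 of 17 cases and later in 0. They included Nr2f2 (3.097), Ednrb, the endothelin receptor of neural crest (2.495, SE 0.33, adjusted p = 9.31e-06), Pou3f3 (1.86), the retinal determination gene Dach1 (1.77) and Pax6, the master factor of eye and forebrain (0.87). The list was called earlier (adjusted p = 0.000325, median 0.87, but adjusted p = 0.268 with an estimated correlation). Genes of fibroblasts moved the same way in 11 of 21 cases and later in 1 (adjusted p = 0.00226, but adjusted p = 0.28 with an estimated correlation). Col1a2, a collagen I chain (chromosome 6, 4400001 to 4600000), went from -1.04 ± 0.011 to 1.51 ± 0.05 (2.71, SE 0.12, adjusted p = 1.52e-11), and the hyaluronan receptor Cd44 lay 2.57 and the matrix protein gene Tgfbi 2.34 above the median window, while Fn1 stood at -1.96. Imprinted genes were called earlier in 9 of 16 cases and later in 1 (adjusted p = 0.0243, but adjusted p = 0.268 with an estimated correlation and lost without scaling), with Peg10 (2.36) and the growth factor gene Igf2 (1.81) earlier and Rasgrf1 (-1.48) later.

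Olfactory receptors were called later in 46 of 76 cases and earlier in 1 (adjusted p = 1.29e-05, but adjusted p = 0.268 with an estimated correlation), and vomeronasal receptors later in 44 of 87 and earlier in 0 (adjusted p = 1.89e-05, but adjusted p = 0.28 with an estimated correlation and lost without scaling). Olfr129 stood at -2.36 and Vmn2r57 at -3.32. All 8 measured genes that escape X inactivation were later (adjusted p = 0.000541, but adjusted p = 0.268 with an estimated correlation), as with Utp14a (-1.63), Kdm5c (-1.60) and Eif2s3x (-1.52), and the X chromosome as a region was called later (adjusted p = 4.79e-06, but adjusted p = 0.268 with an estimated correlation and lost without scaling). Total X signal was lower at day 7 than in ESCs by a difference of -0.26 (adjusted p = 0.000292). Xist, the RNA gene that silences the X, placed between its neighbours, stood at -1.102 (adjusted p = 1.12e-05).

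Primed epiblast genes were 2 earlier and 2 later of 14 at day 7. Fgf5 (1.90) and T (1.40) were the earlier ones. Neither that list (adjusted p = 0.513, with a fitted median of -0.02 against a mean of 0.06 and a test toward earlier) nor those of mesoderm and endoderm genes (4 earlier, 2 later of 14, adjusted p = 0.105), Hox genes (5 earlier of 13, adjusted p = 0.655, median turning to -0.42 without scaling), keratins (9 earlier of 32, adjusted p = 0.253), housekeeping genes (4 later of 14, adjusted p = 0.299) or histone genes (3 later of 4, adjusted p = 0.0778) passed. Without scaling the housekeeping and histone lists were called later (adjusted p = 0.00974 and 0.0409, but adjusted p = 0.329 for both with an estimated correlation). Foxa2 (3.39, SE 0.21, adjusted p = 5.89e-10), the endoderm factor Gata6 (1.71) and Kdr (1.095) were earlier and the fetal serum protein gene Afp (-1.42) later. Among housekeeping genes, Sdha, a subunit of succinate dehydrogenase (-1.99), and the X-linked Pgk1 (-1.61) were later. The housekeeping median was -0.09 as fitted and 0.15 with quantile normalization. The histone gene H2bc23 stood at -2.02, and the protocadherin measured, Pcdha1, at -0.78 (called). Otx2 (0.44), Pou5f1 (0.23) and Actb, placed between its neighbours (0.04), were not called.

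At day 7, 5773 windows (48.3%) differed, 2421 earlier and 3352 later, in 598 and 916 regions with a median length of 0.6 Mb and a maximum of 5.8 Mb and 8.2 Mb. Signs switched from late to early in 825 windows and from early to late in 871. Among the highest regions were those of Slc25a21 (chromosome 12, 57800001 to 58000000, 3.85), Myo16 (chromosome 8, 10600001 to 10800000, 3.83) and Maml3, a Notch coactivator (chromosome 3, 51800001 to 52000000, 3.78). Among the lowest were those of Ptdss1, a phospholipid enzyme (chromosome 13, 67000001 to 67200000, -4.20), and Zfp935 (chromosome 13, 62400001 to 62600000, -3.90). Signal of chromosomes 8 and 12, on which Myo16 and Slc25a21 lie, differed by 0.31 and -0.21 between the ESC arrays. With slide as a block 6626 windows were called and with scan day as a block 6205. Quantile normalization shared 5162 of the calls in direction.

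**Figure D2:**
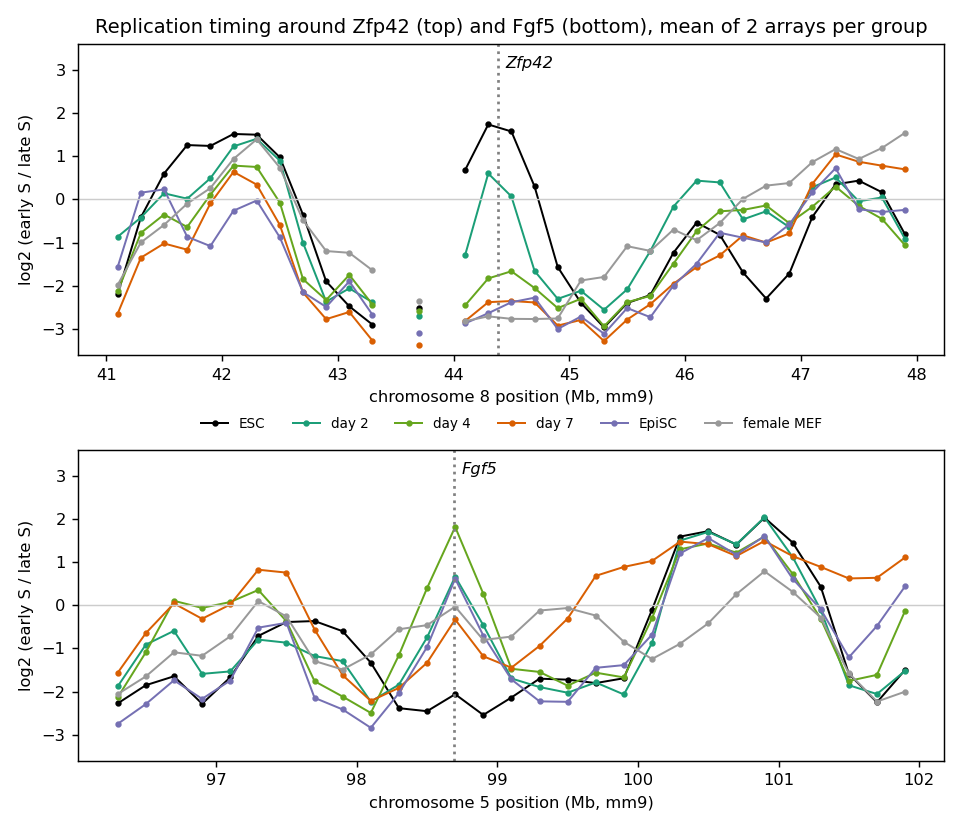
Mean replication timing (log2 early/late, n = 2 arrays per line) along chromosome 8 around Zfp42 and chromosome 5 around Fgf5, in Mb on mm9, for ESC, days 2, 4 and 7, EpiSC and female MEF. The Zfp42 window falls from 1.74 in ESCs to -2.38 at day 7, and the Fgf5 window rises from -2.06 in ESCs to 1.81 at day 4 and lies at -0.33 at day 7.

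The days between show the order of these moves. Zfp42 had left early replication by day 3 (-1.04) and Dppa2 by day 4 (-0.60), while Nanog stayed early until day 6 (0.78). Fgf5 was earliest at day 4 (1.81 ± 0.06). Col1a2 crossed to early by day 4 (0.38) and Ptn by day 6 (0.76), and Ednrb was still late at day 6 (-0.33) and at 0.25 ± 0.40 at day 7. Over the windows that differed at day 7, the median share of the final difference reached was 0.33 at day 2, 0.49 at day 4 and 0.92 at day 6 for the earlier windows, and -0.014, 0.36 and 0.80 for the later ones. Without scaling these shares were 0.49, 0.71 and 0.93 for the earlier windows and 0.14, 0.46 and 0.77 for the later ones. The sign at day 2 of the later windows thus depended on scaling. It also differed between replicate number 1 alone (0.0056) and number 2 alone (-0.030) on the scaled values. The shift of the median window, 0.33 at day 2 and -0.17 at day 7, was not subtracted from these shares. A shift toward earlier at day 2 raises the share of the earlier windows and lowers that of the later ones. The values therefore do not show that the earlier windows moved first. Against ESCs, 5690 windows differed at day 3, 5424 at day 4, 5475 at day 5 and 5195 at day 6. The share called earlier was 64.6%, 62.2%, 59.6% and 47.9%. With centring on the autosomal mean it was 48.4%, 48.5% and 48.9% at days 3, 4 and 5, and with quantile normalization 47.4%, 47.6% and 47.8%.

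Between consecutive days the most windows moved from day 5 to day 6 in the fit of all arrays, where 762 were called earlier and 1111 later. The order of the steps was not examined with arrays left out. The counts were 471 earlier and 762 later from day 2 to day 3, 327 and 395 from day 3 to day 4, 592 and 595 from day 4 to day 5, and 134 and 204 from day 6 to day 7. They sum to 5353 calls, of which 42.7% were earlier. Of 5239 calls without scaling 29.1% were earlier, and of 5341 with centring on the autosomal mean 59.7%. Without day 5 replicate 2 the sum was 3350. With slide as a block the sum was 7826.

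**Figure D3:**
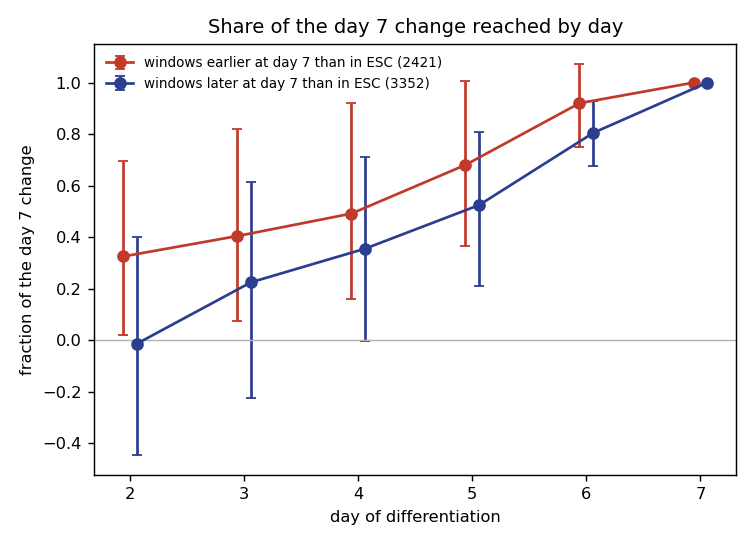
Share of the day 7 minus ESC difference reached at each day (y axis, 0 is ESC and 1 is day 7) for the 2421 windows that became earlier and the 3352 that became later, as medians with bars from the lower to the upper quartile. The median at day 2 was 0.33 for earlier and -0.014 for later windows (0.14 without scaling), and at day 6 it was 0.92 and 0.80. The shift of the median window was not subtracted.

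On the scaled values the mean of the X chromosome was later at days 6 and 7 than in ESCs. Over 685 windows it was -1.11 ± 0.04 in ESCs, -0.90 ± 0.026 at day 2, -1.12 ± 0.018 at day 5, -1.47 ± 0.017 at day 6 and -1.72 ± 0.012 at day 7 (n = 2 each), and windows above 0 went from 25.4% of the X in ESCs to 8.61% at day 7. Against ESCs, day 6 differed by -0.35 (SE 0.065, limma adjusted p = 3.1e-06) and day 7 by -0.60 (adjusted p = 3.94e-16). The day 6 difference turned to 0.091 without scaling (SE 0.0973, adjusted p = 0.435) and was -0.064 with loess (adjusted p = 0.518), while that of day 7 was -0.36 (SE 0.0973, adjusted p = 0.0035) and -0.43. The steps from day 5 to day 6 (-0.35, adjusted p = 4.3e-06) and from day 6 to day 7 (-0.25, adjusted p = 0.00266) both passed, but the latter was -0.15 with centring on the autosomal mean (adjusted p = 0.0625) and -0.16 with quantile normalization (adjusted p = 0.0713). Day 5 had a difference of -0.0044 (adjusted p = 0.996) that depended on scaling. It was 0.49 without scaling (adjusted p = 7.45e-06), 0.46 with loess and 0.19 with normexp, but -0.13 with centring on the autosomal mean (adjusted p = 0.045). Relative to the autosomal mean of the same array day 5 lay at -0.70 and -0.81, later than both ESC arrays (-0.62 and -0.63). At days 2, 3 and 4 the X was called earlier by 0.21, 0.15 and 0.15 (adjusted p = 0.00176, 0.0256 and 0.0356). So were 18, 15 and 9 of the 19 autosomes, with median autosome differences of 0.27, 0.19 and 0.14, and at day 2 13 autosomes differed by more than the X. Relative to the autosomal mean of the same array the X lay at -0.66 and -0.68 at day 2, at -0.70 and -0.63 at day 3 and at -0.57 and -0.66 at day 4, so none of these days was earlier than ESCs in both arrays on that scale. With centring on the autosomal mean days 2 and 3 turned to -0.046 and -0.038 (adjusted p = 0.464 and 0.55). The spread was pooled over 20 chromosomes with 200 degrees of freedom. With the spread of the X alone (10 degrees of freedom) day 7 kept its call (adjusted p = 9.14e-06). The day 7 difference was -0.73 with slide as a block and -0.62 with scan day as a block. At day 7 the means of chromosomes 17 (-0.33, adjusted p = 9.51e-06), 15 (-0.25) and 16 (-0.21) were called later too. Within the scan day of the ESC arrays the X difference of day 7 was -0.61 (1 array), and that of day 6 -0.36.

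Over the 14 arrays of ESC and days 2 to 7, the X mean fell with day (Pearson r = -0.71, permutation p = 0.00518, Spearman rho = -0.67, permutation p = 0.0111, adjusted to 0.0104 and 0.0222 over 2 relations). Without the 2 arrays farthest from the median day, both ESC, r was -0.92 (permutation p = 2e-05). All permutation p-values of this relation treat the 2 arrays of a day as independent and can be too small. The relation was r = -0.80 with slide as a block and r = -0.76 with scan day as a block. It no longer passed without scaling (r = -0.32, permutation p = 0.266) or with loess (r = -0.34, permutation p = 0.238). With normexp it had r = -0.54 (permutation p = 0.049 before adjustment) and rho = -0.52 (permutation p = 0.0596). The other relation of the family, that of the autosomal mean with day, had r = -0.37 (permutation p = 0.192) and rho = -0.47 (permutation p = 0.0946). Total X signal was lower than in ESCs at days 3 to 7, by a difference of -0.30 at day 3, -0.49 at day 5 and -0.26 at day 7 (adjusted p = 7.07e-05, 2.97e-07 and 0.000292), and not at day 2 (-0.0078, adjusted p = 0.88).

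**Figure D4:**
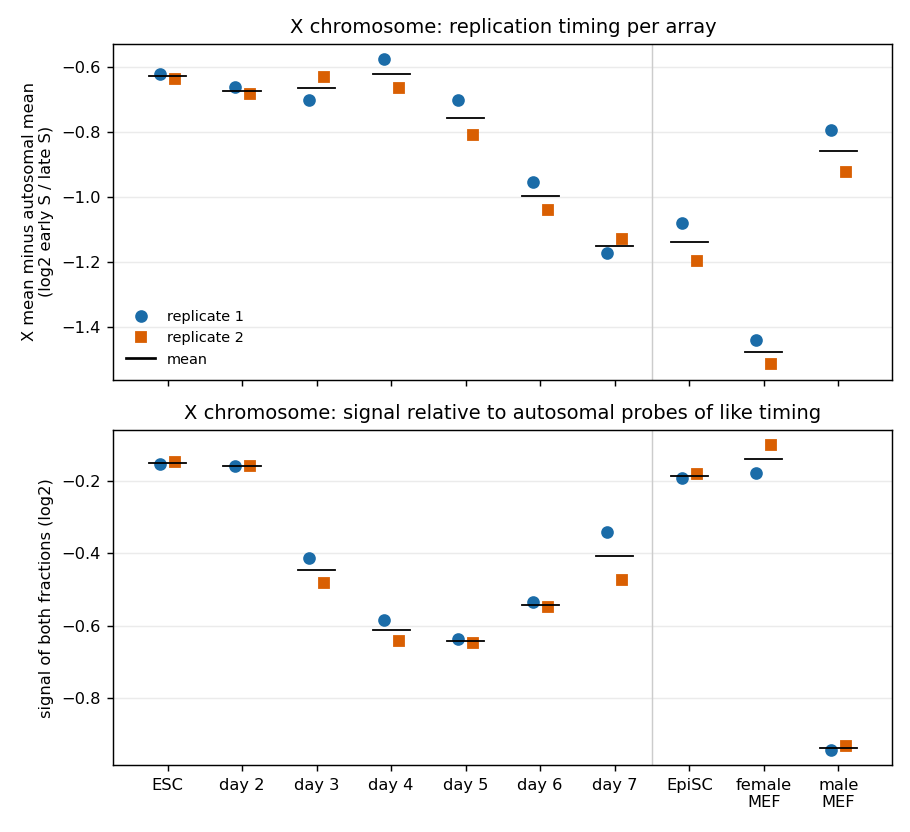
For each array, the X chromosome mean minus the autosomal mean (top, log2 early/late) and X signal relative to autosomal probes of like timing (bottom, log2), with circles for replicate 1, squares for replicate 2 and a line at the mean. The top value falls from -0.62 and -0.63 in ESCs to -1.17 and -1.13 at day 7, and the bottom mean is -0.15 in ESCs, -0.64 at day 5 and -0.94 in male MEFs.

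EpiSCs against ESCs asks how cells of the epiblast after implantation differ from naive cells, with line, strain, slide and scan day changing too. Zfp42 was late in EpiSCs, at -2.63 ± 0.06 (n = 2), and stood at -4.26 relative to the median window (SE 0.12, limma adjusted p = 1.58e-13), while Fgf5 was early at 0.62 ± 0.46 (relative difference 2.79, SE 0.19, adjusted p = 2.61e-09). Of 13 genes of naive pluripotency, 7 were called later and 0 earlier (list adjusted p = 0.00126, but adjusted p = 0.392 with an estimated correlation). Tet2 stood at -3.24, Fbxo15 at -2.73, Dppa2 at -2.48 and Klf4 at -0.92, whereas Nanog (-0.040) and Esrrb (-0.076) were not called. Primed epiblast genes were 4 earlier and 1 later of 14. T (1.49), Eomes, a T-box factor of gastrulation (1.25), and Otx2 (0.96) were earlier, but the list did not pass (adjusted p = 0.46, with a fitted median of -0.13 against a mean of 0.26).

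Neurectoderm genes were called earlier in 8 of 17 cases and later in 0 (adjusted p = 0.00126, but adjusted p = 0.392 with an estimated correlation), with Nr2f2 (2.10), Ptn (2.05), Gli3, a Hedgehog pathway factor (1.92), and Pou3f3 (1.46). Fibroblast genes were 8 earlier and 1 later of 21, with Tgfbi (2.46) and Col1a2 (1.72) earlier and Fn1 (-2.95) later. The fibroblast test was toward earlier (adjusted p = 0.0289, but adjusted p = 0.499 with an estimated correlation and lost without scaling), with a fitted median of -0.0043 and a mean of 0.34. EpiSCs were grown on fibroblast feeders, and whether feeder DNA added to these values was not tested. At day 7 the same list had 11 earlier and 1 later of 21. Olfactory receptors were 1 earlier and 32 later of 76 (adjusted p = 0.00126, but adjusted p = 0.448 with an estimated correlation), and vomeronasal receptors 8 earlier and 40 later of 87 (adjusted p = 0.00146, but adjusted p = 0.499 with an estimated correlation). Both of these calls were lost without scaling. Vmn2r23 (2.77) was earlier and Vmn2r57 (-3.17) later. Of 8 genes that escape X inactivation 7 were later, such as Kdm5c (-2.06) and Utp14a (-1.98) (list adjusted p = 0.00126, but adjusted p = 0.392 with an estimated correlation).

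Imprinted genes were 6 earlier and 2 later of 16 (adjusted p = 0.111), with Igf2 (2.07) and Peg10 (1.73) earlier and Rasgrf1 (-0.97) later. Mesoderm and endoderm genes were 2 earlier and 3 later of 14 (adjusted p = 0.645, with a fitted median of -0.072 against a test toward earlier), with Foxa2 (1.77) and Gata6 (1.20) earlier and Afp (-1.84) and Kdr (-0.71) later. Housekeeping genes were 1 earlier and 3 later of 14 (adjusted p = 0.447, but called later without scaling with adjusted p = 0.0299, and 0.486 with an estimated correlation), histone genes 3 later of 4 (adjusted p = 0.372) and Hox genes 5 earlier of 13 (adjusted p = 0.645, median turning to -0.21 without scaling). Of 32 keratins 0 were called with limma and 0 had an unadjusted p under 0.05 (list adjusted p = 0.73, median turning to -0.23 without scaling). The X mean was -1.67 ± 0.05 in EpiSCs, a difference of -0.56 (adjusted p = 3.71e-14, or 1.4e-05 with the spread of the X alone), and the X as a region was called later (adjusted p = 1.25e-06, but adjusted p = 0.392 with an estimated correlation). Xist stood at -0.73. In all, 4692 windows (39.3%) differed, 2104 earlier and 2588 later. The highest named regions included Maml3 (3.89) and the ETS factor gene Ets1 (chromosome 9, 32400001 to 32600000, 3.66), and the lowest included Trps1 (-4.26) and Zfp935 (-3.90).

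EpiSCs against day 7 asks how epiblast and neurectoderm differ. Nanog was early in EpiSCs (1.55 ± 0.06) and not at day 7 (-0.34 ± 0.22), a difference of 1.89 (SE 0.19, n = 2 each, limma adjusted p = 5.49e-07). Fgf5 lay 0.95 earlier in EpiSCs (SE 0.19, adjusted p = 0.000773), but its EpiSC arrays lay apart (0.62 ± 0.46, against -0.33 ± 0.14 at day 7). Genes of naive pluripotency were 5 earlier and 2 later of 13, with Klf5 (1.04) and the germ cell factor Prdm14 (0.80) earlier and Fbxo15 (-1.16) later. Primed epiblast genes were 4 earlier and 1 later of 14, with Eomes at 0.98. Neurectoderm genes were 1 earlier and 4 later of 17, with Gli3 (1.21) earlier and Dach1 (-1.11) and Nr2f2 (-0.94) later. Ednrb stood at -1.85 and Ptn at -1.41, but both calls were lost when only these 2 groups were fitted. The EpiSC arrays lay far apart there (-1.60 ± 1.23 for Ednrb and -0.65 ± 0.85 for Ptn, n = 2). For EpiSC against day 7, Ednrb was -0.99 without EpiSC replicate 1 and -2.72 without EpiSC replicate 2, and Ptn -0.81 (call lost, adjusted p = 0.065) and -2.01. Mesoderm and endoderm genes were 1 earlier and 4 later of 14, with Kdr at -1.75 (SE 0.14, adjusted p = 5.07e-08) and Foxa2 at -1.56. Fibroblast genes were 3 earlier and 8 later of 21, with the microfibril gene Fbn1 (1.23) earlier and the collagen cross-linking enzyme gene Lox (-1.45), the proteoglycan gene Dcn (-1.21) and Col1a2 (-0.94) later. Vomeronasal receptors were 18 earlier and 3 later of 87, olfactory receptors 14 earlier and 2 later of 76 (14 called when adjusted over the list alone), imprinted genes 2 earlier and 7 later of 16, keratins 3 later of 32 and histone genes 3 earlier of 4. The vomeronasal median turned to -0.041 without scaling. In all, 3716 windows (31.1%) differed, 1845 earlier and 1871 later (2426 when only these groups were fitted), and the highest regions included the potassium channel genes Kcnq3 (chromosome 15, 66000001 to 66200000, 3.58) and Kcnj3 (chromosome 2, 55400001 to 55600000, 3.42) and the lowest 4930524C18Rik (-3.76), Lrmda (-2.996) and Glis3 (-2.95). The X mean did not differ (0.045, adjusted p = 0.787). Against day 2, 6818 windows differed in EpiSCs, 1668 earlier and 5150 later (24.5% earlier, but 44.3% with centring on the autosomal mean and 45.6% with quantile normalization). Of the primed epiblast genes 1 was then earlier and 10 later, but the median window stood at -0.42, 7 of the later ones lay over 0.5 below it, and with quantile normalization 1 was earlier and 4 later.

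Female MEFs against ESCs asks how a differentiated cell type departs from naive cells, again with strain, slide and scan day changing too. Cd44 went from -2.13 ± 0.17 to 1.92 ± 0.20 (n = 2 each, relative difference 4.19, SE 0.14, limma adjusted p = 4.07e-13). The mesenchyme factor Prrx1 (4.09), the collagen gene Col3a1 (4.05), smooth muscle actin Acta2 (3.97) and Lox (3.79) moved with it. Of 21 fibroblast genes 15 were called earlier and 1, Tagln (-0.70), later (adjusted p = 1.32e-08, median 2.66, but adjusted p = 0.181 with an estimated correlation). Of 13 genes of naive pluripotency 11 were called later and 0 earlier (adjusted p = 2.68e-05, but adjusted p = 0.209 with an estimated correlation), with Zfp42 at -4.30 (SE 0.12, adjusted p = 1.19e-13), Dppa2 at -3.03, Prdm14 at -2.43, Nanog at -1.33 and Esrrb at -1.15, while Klf4 (-0.24) was not called. Primed epiblast genes were 1 earlier and 6 later of 14 (adjusted p = 0.18, but called later without scaling with adjusted p = 0.00476, and 0.303 with an estimated correlation), with Otx2 (-1.24) and the DNA methyltransferase gene Dnmt3b (-1.13) later and Fgf5 (2.17) earlier. Neurectoderm genes went both ways, 4 earlier and 5 later of 17 (adjusted p = 0.753, median turning to -0.049 without scaling), with Ptn (3.37) and Gli3 (2.81) earlier and Lhx5 (-1.28), Zic2 (-1.08) and Pax6 (-0.87) later.

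Histone genes were later in 4 of 4 cases (adjusted p = 0.0324, but adjusted p = 0.302 with an estimated correlation), such as H2bc4 (-2.502). Mesoderm and endoderm genes were 6 earlier and 3 later of 14 (adjusted p = 0.205, median turning to -0.57 without scaling), with Dab2 (2.73), Foxa2 (2.28) and the signalling gene Bmp4 (2.06) earlier and Tbx5 (-1.07) later. Olfactory receptors were 0 earlier and 44 later of 76 (adjusted p = 2.68e-05, but adjusted p = 0.302 with an estimated correlation), and vomeronasal receptors 2 earlier and 59 later of 87 (adjusted p = 1.15e-05, but adjusted p = 0.302 with an estimated correlation). Without scaling the fitted medians of both receptor lists turned to 0.22 and 0.41, but they stayed below the median window (0.47) and both tests stayed toward later. Both camera calls were lost (adjusted p = 0.812 and 0.958). All 8 genes that escape X inactivation were later (adjusted p = 0.000619, but adjusted p = 0.181 with an estimated correlation). Imprinted genes were 6 earlier and 2 later of 16 (adjusted p = 0.598, with a fitted median of -0.059 against a mean of 0.074), with Igf2 (1.97) earlier and Rasgrf1 (-2.34) later. Keratins were 12 earlier of 32 (adjusted p = 0.18, median turning to -0.32 without scaling), housekeeping genes 5 later of 14 (adjusted p = 0.18, but called later without scaling with adjusted p = 0.000439, and 0.206 with an estimated correlation) and Hox genes 0 of 13 with limma and 0 at an unadjusted p under 0.05 (list adjusted p = 0.753, median turning to -0.84 without scaling).

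In all, 6936 windows (58.1%) differed in female MEFs, 3065 earlier and 3871 later, and 7608 in male MEFs, 3083 earlier and 4525 later. The share earlier was 44.2% and 40.5%, but 56.6% of 10102 calls and 56.0% of 10095 calls without scaling. The highest named regions included Fbn2 (chromosome 18, 58200001 to 58400000, 4.51) and Dnm3 (chromosome 1, 164000001 to 164200000, 4.47), and the lowest included the window of Zfp42 (-4.30) and Fxr1 (chromosome 3, 33800001 to 34000000, -4.25). The X mean of female MEFs was -1.95 ± 0.023, a difference of -0.83 from ESCs (adjusted p = 8.44e-27, or 1.33e-06 with the spread of the X alone). That difference turned to 0.058 without scaling, where the median window stood at 0.47. Scaling an array does not change the sign of its windows. X windows with a mean above 0 made up 25.4% in ESCs, 0.438% in female MEFs and 22.3% in male MEFs. Of autosomal windows 42.2%, 43.9% and 44.6% lay above 0. Fewer X windows were thus early in female MEFs than in ESCs, a result that does not rest on scaling. On the scaled values, relative to the autosomal mean of the same array, the X lay at -1.44 and -1.515 in female MEFs. It lay at -0.62 and -0.63 in ESCs. The X as a region was called later (adjusted p = 5.78e-09, but adjusted p = 0.211 with an estimated correlation), and its direction turned without scaling (adjusted p = 0.958). Xist stood at -1.69.

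**Figure D5:**
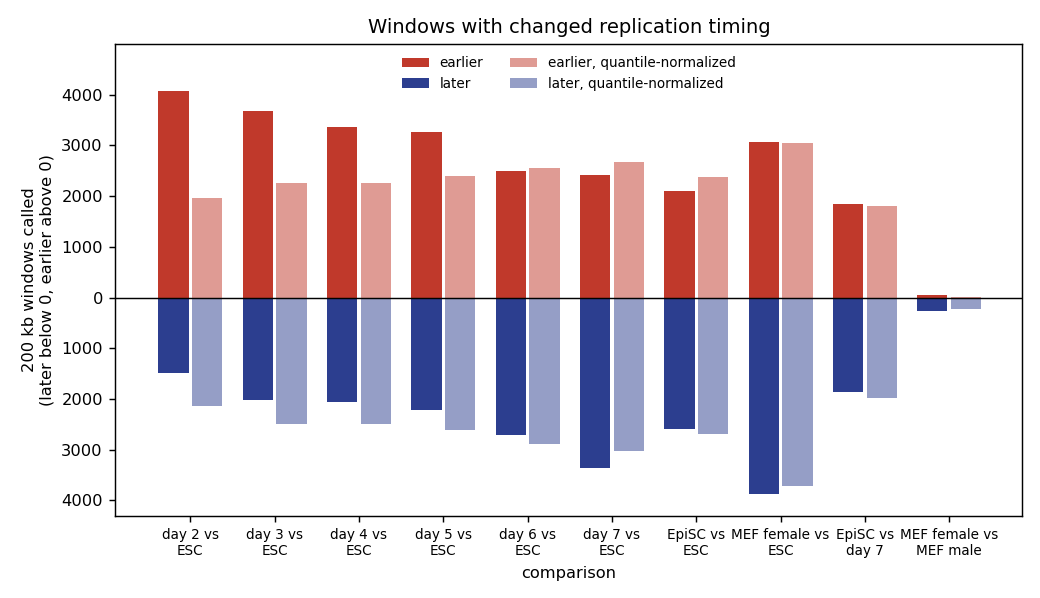
Number of 200 kb windows called earlier (above 0) and later (below 0) in each of 10 comparisons, with paler bars for quantile normalization. At day 2, 4079 windows were earlier and 1496 later, against 1971 and 2144 with quantile normalization, and at day 7 2421 and 3352.

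Female against male MEFs, all on 1 slide, asks what differs between the sexes in 1 cell type. Each sex appears to be 1 isolate with 2 arrays, so sex and isolate cannot be told apart here. The X chromosome replicated later in female cells, at -1.95 ± 0.023 against -1.42 ± 0.04 (n = 2 each), a difference of -0.53 (SE 0.065, limma adjusted p = 4.76e-13, or 1.72e-05 with the spread of the X alone). Total X signal was 0.80 higher in female cells (adjusted p = 1.13e-09). Of 685 X windows 263 (38.4%) were called later and 0 earlier, and of the autosomal windows 45 (0.40%) were called earlier and 0 later. At an unadjusted p under 0.05 limma gave 1672 windows, and with only these groups fitted 198 were called. In 150 windows, all from early to late, the sign switched. Share earlier was 14.6% of 308 calls, but 0% of 148 without scaling, 3.18% of 220 with loess and 46.0% of 467 with centring on all probes. The window of Tmem164 (chromosome X, 139000001 to 139200000) stood at -0.65 ± 0.12 in female and 1.68 ± 0.21 in male cells, a difference of -2.33 (SE 0.16, adjusted p = 9.12e-08) inside a region of 5 Mb. Zdhhc9 (chromosome X, 45400001 to 45600000) differed by -2.03. The X-linked housekeeping genes Hprt (-1.74, SE 0.15, adjusted p = 3.76e-07) and Pgk1 (-1.31) were later in female cells. Xist had 0.17 ± 0.05 in female and 0.70 ± 0.43 in male cells.

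Of 8 measured genes that escape X inactivation, 4 were called later in female MEFs (6 when adjusted over the list alone), namely Eif2s3x, a translation factor subunit (-1.77), Utp14a (-1.65), the histone demethylase gene Kdm5c (-1.36) and 5530601H04Rik (-0.53, adjusted p = 0.0447). The last call was lost under several alternatives. The list test passed (adjusted p = 2.27e-14, and adjusted p = 0.00147 with an estimated correlation), as did that of the X as a region (adjusted p = 1.36e-91, and adjusted p = 0.000538 with an estimated correlation). Fibroblast genes had a test toward earlier in female cells (adjusted p = 0.000127, median 0.32, but adjusted p = 0.368 with an estimated correlation, which became 0.0238 without scaling), with 0 of 21 members called with limma, 2 when adjusted over the list alone and 9 at an unadjusted p under 0.05. With quantile normalization the fibroblast median was 0.11. All windows of this list lay above 0 in both sexes. The 95th percentile of autosomal windows was 1.89 in female and 1.61 in male MEFs, so part of the median may come with that wider range. Vomeronasal receptors had 0 of 87 members called with limma and 9 at an unadjusted p under 0.05, and a test toward earlier (adjusted p = 0.0146, but adjusted p = 0.944 with an estimated correlation and lost without scaling). Housekeeping genes had a median of 0.20 and a mean of -0.011, with a test toward later that did not pass (adjusted p = 0.747). Over the 5 tested comparisons 28 list calls were made, and 2 of them held with an estimated correlation, both in this comparison. The escape genes lie on the X, and camera set both lists against all windows, so these 2 calls are not separate results. Escape genes were not tested against the rest of the X in any comparison.

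Comparisons against ESCs share the same 2 control arrays, which were not split because each comparison would have kept 1, so part of any likeness between them may come from those controls. Day 7 and EpiSCs shared 1428 earlier and 1941 later windows, against 426.6 and 726.5 for independent lists of the same sizes, with 217 in opposite directions. Their differences correlated across windows at r = 0.745 with a covariance of 0.623. Simulated groups without change gave a mean r of 0.324, a highest r of 0.777 and a covariance of 0.0066 in 100 simulations, with 0 shared calls. Groups without change leave few calls to share, so this 0 does not measure what the shared controls add to the overlap. All correlations of this kind given here lay below the highest simulated r, and that of days 2 and 7 lay near the simulated mean. The simulated differences held only spread between arrays, so their r cannot be set against that of differences that hold change. Covariances can be compared, and those given here (0.220 to 0.777) lay far above the simulated mean of 0.0066. Spread of the simulated size in the shared controls thus gave only a small part of them. Day 7 and female MEFs shared 1653 earlier and 2249 later windows (621.4 and 1087 for independent lists, r = 0.661, covariance 0.777, 422 opposite). EpiSCs and female MEFs shared 1240 and 1601 (540.1 and 839 for independent lists, r = 0.497, covariance 0.521, 634 opposite). Days 2 and 7 shared 1016 earlier and 836 later windows (827 and 419.9 for independent lists, r = 0.338, covariance 0.220), and 805 went in opposite directions.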

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

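The tests of slide, of a missing X chromosome and of DNA outside the sorted fractions for the X signal, and the tests of dye and slide for chromosome 8, were chosen only after the result was seen, while the test of an extra chromosome 8 was written before.

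X signal, the brightness of X probes in both channels relative to autosomal probes of like timing, was no part of the timing comparisons and was lower at day 5 than in ESCs by a difference of -0.491 (limma adjusted p = 2.97e-07, n = 2 each) and also lower at days 3, 4, 6 and 7, while no autosome other than chromosomes 8 and 12 differed between any of these groups and ESCs by more than 0.0667. A slide or scan batch is argued against, since the day 3 array on the slide of the ESC arrays stood at -0.259 relative to the mean of the other 3 arrays of that slide, whose SD was 0.00575. All 17 bins of 10 Mb along the X were lower at day 5, between -0.702 and -0.299. They were also lower at day 3 (-0.588 to -0.114) and day 7 (-0.674 to -0.149). A missing X chromosome in part of the cells of these cultures predicts this, a hypothesis found and tested on the same arrays. Any other fall along the whole X predicts it too, so the bins cannot tell these causes apart. Mean X signal was -0.642 at day 5, -0.541 at day 6 and -0.407 at day 7. X DNA that replicated outside the sorted early and late fractions stays open, because the correlation of signal change with timing change across X windows (r = -0.279) does not decide it. If part of the cells lacked an X, the X timing of days 6 and 7 may be measured on a changing mixture of cells, although X signal rose by 0.133 from day 6 to day 7 (adjusted p = 0.0428) while X timing went later.

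Chromosome 8 signal differed between arrays of the same group, by 0.308 between ESC replicates 1 and 2, where the SD of replicate differences of the other autosomes was 0.0202. Dye orientation is argued against, since day 2 had the opposite sign (-0.261), and a slide or scan batch is argued against, since both ESC arrays lay on 1 slide. The difference held in 14 of 14 bins of 10 Mb, from 0.157 to 0.368. An extra chromosome 8 in part of the cells of some cultures predicts this. Chromosome 12 differed too (-0.207 in ESCs and 0.126 at day 2). Its mean signal was 0.146 in ESCs, 0.148 at day 3 and 0.251 at day 7, against 0.006 in EpiSCs and 0.024 in female MEFs. EpiSCs differed from day 7 by -0.245 there (limma adjusted p = 0.0034), with line, strain and slide changing too. The cause was not tested. The differences of 0.308 and -0.261 on chromosome 8 argue against 2 arrays of the same DNA in ESCs and at day 2. They do not bear on the other groups. No biological explanation was tested beyond an extra chromosome 8, and the labels do not describe karyotypes.

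The other values that stood out are given without explanation. The X chromosome mean differed by -0.5324 between female and male MEFs, a difference between groups measured against the same ESC arrays. The change against ESCs differed between EpiSCs and day 7 in 3716 windows. At days 2 and 7, 805 windows were called in opposite directions against ESCs. Signal of the 122 Y probes relative to autosomes, outside the main measurement, averaged -0.669 in male MEFs (-0.844 and -0.495), against -4.385 to -3.01 in all other arrays.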

How the results depend on the processing

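Quantile normalization, centring on the autosomal mean, scan day as a block, the X spread alone, days 2 to 7 alone and members placed between neighbours were tests chosen after seeing the data, as were all alternatives for the X mean in comparisons other than day 7, EpiSCs and female MEFs with ESCs and female with male MEFs. With 2 arrays per group, leaving out 1 leaves a lone array that is assumed to vary like the other groups. Signal over background was high on all arrays, and leaving out dim probes changed no call, direction or count of a main result fixed beforehand by over 1.5 times. Of 7612 values of named genes under alternatives fixed beforehand, 7278 kept direction and side of the threshold, 293 lost a call, 34 gained one and 7 reversed, and of 1119 under added alternatives 1054, 52, 8 and 5. Unless said otherwise the cause was not tested. The counts below run in the order days 2, 3, 4, 5, 6 and 7, EpiSC and female and male MEF against ESC, EpiSC against days 7 and 2, female against male MEF, and the sum over consecutive days.

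Windows of 100 kb, more of which were tested, gave 10476, 10688, 10349, 10468, 9697, 10631, 8706, 12736, 13949, 6856, 12644, 632 and 8879 calls. Windows of 500 kb, fewer of which were tested, gave 2190, 2193, 2103, 2131, 2070, 2342, 1897, 2892, 3179, 1476, 2819, 127 and 2026, and 959 regions at day 7 in place of 1514. A size minimum of 1, which is stricter by construction, gave 1593, 2205, 1977, 2081, 2592, 2970, 2451, 4059, 4513, 1503, 2813, 163 and 551.

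Without scaling, days 3 to 6 had 9282, 8758, 8406 and 8049 calls and female against male MEF 148. The X difference of female MEFs from ESCs reversed to 0.05813 and the test of the X as a region turned toward earlier (adjusted p = 0.958), the relation of X with day weakened to r = -0.319, and the share of the day 7 change reached by day 5 was 0.6695 in place of 0.59. With loess that relation was r = -0.3372 and the lowest correlation between replicates 0.9458 in place of 0.962. Centring on all probes gave 467 calls for female against male MEF. With only the compared groups, which leaves fewer arrays for the spread, EpiSC against day 7 had 2426 and female against male MEF 198. With an estimated correlation 2 of 28 list calls were left.

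The X mean depended on scaling in further comparisons. Without scaling it reversed to 0.4888 at day 5, 0.09148 at day 6, 0.5403 in male MEFs, 0.2028 from day 2 to day 3, -0.07391 from day 3 to day 4 and -0.0786 for EpiSC against day 7. With normexp it reversed to 0.1876 at day 5, 0.1169 from day 2 to day 3, -0.02628 from day 3 to day 4 and -0.008104 for EpiSC against day 7, and with loess to 0.4587 at day 5, 0.2922 from day 2 to day 3 and -0.1065 for EpiSC against day 7. With centring on the autosomal mean it reversed to -0.04551 at day 2, -0.03826 at day 3 and 0.007246 from day 2 to day 3, and with quantile normalization to -0.04171, -0.01802 and 0.02369. Where the fitted X difference was near 0 it also reversed at day 5 with 500 kb windows (0.007247) and from day 3 to day 4 with centring on all probes (-0.001284), 100 kb windows (-0.005872), window medians (-0.003993), without dim probes (-0.004084), at least 10 probes (-0.03166) and slide as a fixed (-0.07559) or random block (-0.04214). At day 4 it turned to -0.00442 with slide as a block. Leaving out 1 array it ran from -0.03265 to 0.02394 at day 5, from -0.1742 to 0.05882 from day 2 to day 3 and from -0.1163 to 0.1166 from day 3 to day 4.

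Single genes reversed as follows. With 500 kb windows Bmp4 turned to 0.2887 at day 2 and 0.2575 in EpiSCs, Vim to -0.04195 at day 7, and Vmn1r32 to -0.5369 in female MEFs and 0.03937 for EpiSC against day 7. With quantile normalization at day 2, Xist, Jpx and Ftx turned to -0.07009, Nr5a2 to -0.1507 and H3c14 to -0.3025. Without scaling H3c14 turned to -0.03762 at day 2 and Snrpn to 0.7401 in female MEFs.

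Leaving out 1 array at a time gave 4946 to 5518 calls at day 2, 4774 to 6254 at day 3, 4910 to 5254 at day 4, 5001 to 5430 at day 5, 4716 to 4952 at day 6 and 5171 to 5766 at day 7. It gave 4276 to 5237 for EpiSC against ESC, 6327 to 6784 for female and 7144 to 7665 for male MEF, 3075 to 4679 for EpiSC against day 7, 6239 to 7463 against day 2, 232 to 305 for female against male MEF and 3350 to 4874 for consecutive days, the lowest without day 5 replicate 2. The X difference ran from -0.6323 to -0.5757 at day 7, -0.5907 to -0.5265 in EpiSCs, -0.8628 to -0.8062 in female MEFs and -0.5591 to -0.5057 between MEF sexes, and r with day from -0.7903 to -0.6432.

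With the replicate number as a block the counts were 5644, 5738, 5475, 5521, 5234, 5818, 4724, 6992, 7643, 3779, 6873, 340 and 6105, with 28 list calls, an X difference of -0.604 at day 7 and r = -0.7094 with day, and no main result changed its call or direction. Arrays with the same number deviated together by more than 0.1 in 24 of 45 pairs of groups (correlations from -0.366 to 0.568). The numbers mark the dye orientation, so pairing and a dye effect cannot be told apart, and the numbers were not taken to pair the samples. As a hint from the data, 18 of 20 arrays correlated best with their own number. At each of days 2 to 7 the 2 numbers also lay on different slides and scan days. Replicate 2 of days 3, 4, 5 and 6 shared the same slide and scan day.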

Other observations

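The windows named here and the test of slide for timing boundaries were chosen after their values were seen, while the tests of probe noise and centring were written before. Many windows had moved one way by day 4 and went back part or all of the way by day 7. The rule used only ESC, day 4 and day 7, so a window may have turned back before day 4. Between ESC and day 4, 2051 windows became earlier and then later again by day 7 (818 with quantile normalization, 790 in both settings), and 518 did the reverse (714 with quantile normalization, 451 in both). Of these, 1692 and 347 were not called at day 7 against ESC (548 and 485 with quantile normalization). The window of Clcn1, the skeletal muscle chloride channel gene (chromosome 6, 42200001 to 42400000), stood at -1.72 in ESCs, 0.50 at day 2, 1.31 at day 4 and -1.54 at day 7 (day 4 minus ESC 3.04, SE 0.20, limma adjusted p = 1.37e-09, and day 7 minus day 4 -2.86, adjusted p = 1.03e-08, n = 2 each). Emb (chromosome 13, 118000001 to 118200000) was at -1.89, 1.45, 1.21 and -1.10 at the same stages, and Myo3a, a myosin gene of hair cells (chromosome 2, 22000001 to 22200000), at -2.52, -1.23, -0.29 and -2.81. Lypd6 (2.87 at day 4 and -2.13 from day 4 to day 7) and the window that holds Fgf5 (3.87 and -2.14) rose and then fell, and like Emb they ended above their ESC values (-0.39 against -1.13 and -0.33 against -2.06).

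In the other direction, Fndc3b (chromosome 3, 27400001 to 27600000) went from 0.96 in ESCs to -0.83 at day 2 and -1.55 at day 4 and was at 0.24 by day 7 (day 4 minus ESC -2.51, SE 0.16, adjusted p = 1.04e-09). Icos, a costimulatory receptor gene of T cells, changed by -1.98 to day 4 and by 1.88 after it, and the zinc finger gene Bnc2 by -1.91 and 1.77. Zeb1, a zinc finger factor of epithelial-to-mesenchymal transition (chromosome 18, 5600001 to 5800000), was late in ESCs (-0.997), later at day 4 (-2.21) and at -0.40 at day 7. Of the windows called in opposite directions at days 2 and 7, 619 were earlier first and 186 later first, and 257 and 148 of these were also found with quantile normalization.

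The number of timing boundaries, counted as neighbouring windows on either side of 0, fell from 1481 and 1436 at day 2 to 1049 and 968 at day 7, with 1180 and 1181 in ESCs, 1154 and 1122 in EpiSCs and 1027 to 1110 in MEFs. Over the 12 arrays of days 2 to 7 the Pearson correlation with day was -0.97 and Spearman's rho -0.96 (permutation p = 1e-05 for both, the smallest these permutations can give, adjusted to 1.33e-05 and 2e-05 over 4 measures), and r was -0.96 without the 2 arrays farthest from the median day. Single arrays were shuffled although the 2 arrays of a day go together. These p-values are therefore smaller than the number of days allows. Probe noise as the whole cause is argued against, since smoothing over 5 windows gave r = -0.9853. Smoothed counts fell less, from 775 and 773 at day 2 to 651 and 627 at day 7, and ESCs then had 770 and 768, so how far noise added to the unsmoothed fall, and to the higher count of day 2 than of ESCs, stays open. Centring is argued against, since crossings of each array's own median gave r = -0.9688. A slide or scan batch is argued against by 3 of 3 slides on which the latest day had fewer boundaries than the earliest. No biological explanation of this fall, seen in 1 cell line, was tested.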
